A study of Schizosaccharomyces pombe with 15 samples.

How the data were processed

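Libraries were made from total RNA of logarithmically growing cells kept at 30 °C with shaking at 150 rpm, per the labels' protocols. RNA was treated with PNK except in 2 libraries, 3 µg were ligated to 120 pmol of a 3′ adapter, and from 1 µg of the ligation product cDNA was made and amplified with a U6 primer or a primer for tagged U6, per the labels. The deposited files list counts: each line holds the number of reads and the sequence of the end after the constant part of U6. CASAVA 1.8.2 and cutadapt are named in the submitters' processing notes, with no role or order. The steps that separated endogenous from tagged U6, the filters on reads and the genome build are not given in the sources used here. Which of the 2 files of a tagged strain held tagged U6 was taken from the word exogenous in its name. The values are raw counts of reads, with no normalization, and they were not corrected for PCR duplicates, since the protocol describes no molecular identifiers. Amplification and ligation can favour some ends over others, so shares describe the sequenced products.

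Each file had 1 line with counts but no sequence, holding 0.112% to 6.78% of its reads. That line names no end, so it was left out of all shares and was reported apart as reads with no base past the constant part. This reading of the line is an assumption and was not checked. The remaining ends were sorted into classes fixed before the data were examined: Us alone, Us followed by As alone, Us followed by any other tail, at least 8 Us followed by the downstream genomic sequence, and ends that do not start with a U. The limit of 8 Us and the last class were set after the files had been seen. The planned class of ends inside the U6 body was taken from the line with no sequence. The U run was measured on reads of the first 2 classes, which held 90.1% to 98.5% of reads. DNA letters were read as RNA, T for U. The constant part, the T run and the gene were placed on the ASM294v3 reference by exact matches of the primer and of reads that continue downstream. That reference served for coordinates only.

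Groups were taken from the sample titles, which gave 1 library per group. No test was made between single libraries and no p-value was made from reads. Shares have exact (Clopper-Pearson) 95% intervals, and the interval of a difference between effects combines the interval widths of its 4 shares. The effect of mpn1 deletion was tested with a two-sided exact sign-flip test over 5 background pairs and a two-sided exact permutation test of 8 against 5 libraries, with Benjamini-Hochberg adjustment over 5 outcomes. Tagged and endogenous U6 were compared with a sign-flip test over 4 strains, adjusted over 6 outcomes. The ends named in the text were chosen by a rule fixed in advance: the 3 commonest ends of each library, every end with at least 5% in any library, and the 3 largest rises and falls of each comparison. The sum of ends with 1 to 3 Us, the ratios of ends without PNK to those with it and the 4-nt ends, with or without a C after them, were chosen after their values were seen.

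The class assignment and the means were tested on simulated data: 100 of 100 simulated libraries of 408281 reads were recovered within 0.5 percentage points and 0.02 nt. These libraries held only ends built from the class definitions, with no tails of at least 2 As and no read errors, so this checks the computation alone. Of 200 unchanged draws of 8 against 5 values from a normal distribution, 9 had an exact p under 0.05. Alternatives tried were ends with at least 10 reads, each distinct end with at least 2 reads counted once (ends seen once, 44.9% to 72.7% of the distinct ends of a file, were left out), ends that reach the U run, the median U run, A tails of at least 2 As, subsets of strains, and each pair or library left out in turn. Further alternatives, chosen after seeing the data, counted the line with no sequence as an end with 0 Us, left out ends of 4 and 19 nt, read ends of 5 nt in C without the C, or left out files in doubt. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

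Libraries fell into sets by the share of reads whose end held an N. It was at most 0.000142% in 7 untagged libraries, 0.0217% to 0.0244% in wt without PNK, cid11Δ, cid12Δ and cid16Δ, and 0.00249% to 0.00598% in the 8 files of tagged strains. The labels give no batch or date.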

Results

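The 3′ ends of U6 small nuclear RNA were read in fission yeast, Schizosaccharomyces pombe, by 3′ RACE: an adapter was ligated to the ends of total RNA, U6 was amplified from it and the products were sequenced. U6 is the spliceosomal RNA that RNA polymerase III transcribes and that ends in a run of Us. The series held 15 libraries, each the only library of its strain or treatment, so no value has a replicate of its own. There were 11 libraries of untagged strains and 4 of strains that carry a tagged U6 beside the endogenous one, and 13 of the 15 were treated with polynucleotide kinase (PNK), which removes 3′ phosphates that block ligation. The 4 tagged strains gave 1 file for endogenous and 1 for tagged U6, which made 19 files. Each held between 408281 and 3966962 reads with an end sequence. The exact (Clopper-Pearson) 95% interval of a class share was at most 0.143 percentage points to either side. For a count of 0 in the shallowest file it allowed a share of up to 0.000904%. These reads are PCR products without molecular identifiers, so intervals and limits cover counting error only. A difference between single libraries was held to a size limit fixed before the data were examined: at least 5 percentage points and 1.5 times for a share, and at least 0.5 nt for a mean U run.

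The U6 gene, snu6, lies on the minus strand of chromosome I, from 2562276 to 2562419 in the ASM294v3 assembly. Its exon 1 runs from 2562374 to 2562419 and its exon 2 from 2562276 to 2562323, with an intron of 50 nt between them. The annotated gene stops before an A at 2562275 and the encoded run of 9 Ts at 2562266 to 2562274. Among the 3639 reads that ran on into the genomic sequence after the T run, 94.8% had 9 Ts before it. These reads were pooled over all files, tagged U6 included. The class of at least 8 Us followed by downstream sequence held 1864 reads in tagged U6 of tU6-wt and 981 in that of tU6-C36A. It held 25 and 0 in tagged U6 of the strains without mpn1, and at most 365 in any endogenous file. By the reference sequence, an A that follows fewer than 9 Us is not encoded at this locus.

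In wt, U6 ended mainly in Us. Oligo-U ends, made of Us alone, held 92.5% of reads (95% interval 92.4 to 92.5), and ends with Us followed by As, called adenylated here, held 4.55% (4.51 to 4.60). The commonest end had 5 Us, with 55.0% of reads, followed by 6 Us with 11.9% and 4 Us with 7.35%. The mean U run was 4.53 nt. Of adenylated reads in wt, 93.4% carried a single A. Reads listed with no sequence, taken here to have no base past the constant part, made up 3.22% of all reads.

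**Figure D1:**
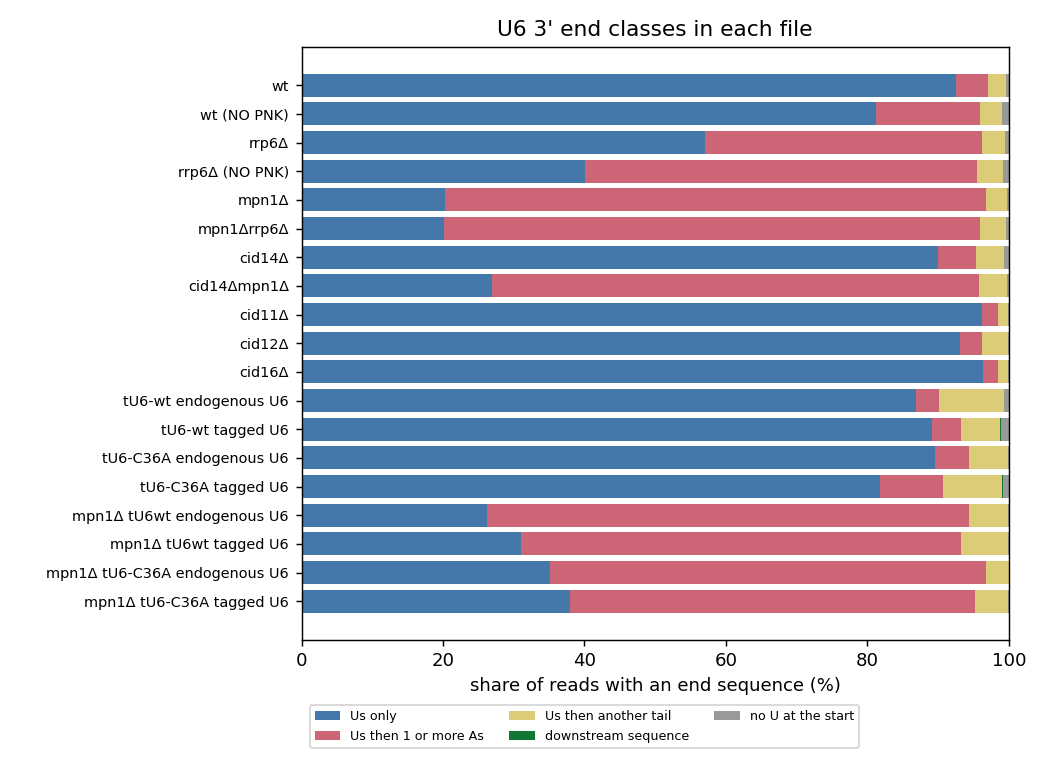
Share of reads with an end sequence (horizontal axis, %) in each end class for the 19 files (vertical axis), with 1 library per strain or treatment and no error bars. Adenylated ends outnumber oligo-U ends in 8 of the 19 files, which are the 7 files of mpn1-deleted strains and that of rrp6Δ without PNK.

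To ask which enzymes shape these ends, the series set 6 single deletions against wt. Deletion of mpn1, which encodes the fission yeast homolog of the human U6-trimming exoribonuclease USB1, gave the largest difference of the 6 in adenylated ends, at 76.5% of reads (76.4 to 76.5) against 4.55% in wt. The end with 5 Us and 1 A rose from 1.33% to 35.1% and that with 6 Us and 1 A from 0.801% to 23.1%, while the plain 5-U end fell from 55.0% to 5.51%. Deletion of rrp6, which encodes a 3′-5′ exonuclease of the nuclear exosome, gave 39.1% adenylated ends (39.0 to 39.2). There the end with 5 Us and 1 A held 19.6% and the 5-U end 28.1%. Both differences in adenylated share were past the size limit, and those of the other 4 deletions were not. With each distinct end of at least 2 reads counted once, the differences were -0.463 points for mpn1Δ and -0.137 points for rrp6Δ, so both rest on how many reads the ends held.

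Deletion of cid14, which encodes the non-canonical poly(A) polymerase of the TRAMP complex, left 5.39% of reads adenylated (5.32 to 5.45). More of its reads ended early: the 1-U end held 12.2% against 7.14% in wt, the 2-U end 9.15% against 5.47%, and the 5-U end 41.6% against 55.0%. Ends with 1 to 3 Us together held 27.2% of reads in cid14Δ and 16.2% in wt, and the mean U run was 4.09 nt against 4.53 nt, a difference under the limit. Reads with no base past the constant part made up 6.78% of all reads against 3.22%, also under the limit. When those reads were counted as ends with 0 Us, an alternative chosen after seeing the data, the difference in mean U run was -0.581 nt and passed the limit. It turned to 0.456 nt with each distinct end of at least 2 reads counted once, so the direction rests on how many reads the ends held.

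In the strains without cid11, cid12 or cid16, which encode nucleotidyltransferases of the Cid1 family, ends were gathered at 5 Us. The 5-U end held 86.1% of reads in cid11Δ, 78.7% in cid12Δ and 84.5% in cid16Δ. Ends with 1 to 3 Us held 0.811%, 1.13% and 1.25%, against 16.2% in wt. The 6-U end was also lower than in wt, at 0.526, 0.743 and 0.683 times its share. Adenylated ends held 2.34%, 3.12% and 2.07%. The mean U run was 0.485, 0.503 and 0.496 nt longer than in wt, so that only cid12Δ passed the limit, with 0.492 nt when ends of 4 and 19 nt were left out. All 3 passed, with 0.629, 0.646 and 0.638 nt, when reads with no base past the constant part were counted as 0 Us, an alternative chosen after seeing the data. None was longer past the limit with each distinct end of at least 2 reads counted once: the differences were -0.135, 0.341 and -0.677 nt, that of cid16Δ past it the other way. These 3 libraries had a base called N in 0.0217% to 0.0226% of reads, whereas wt had none, so the comparison crosses library sets that differ technically, and set and deletion cannot be told apart.

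**Figure D2:**
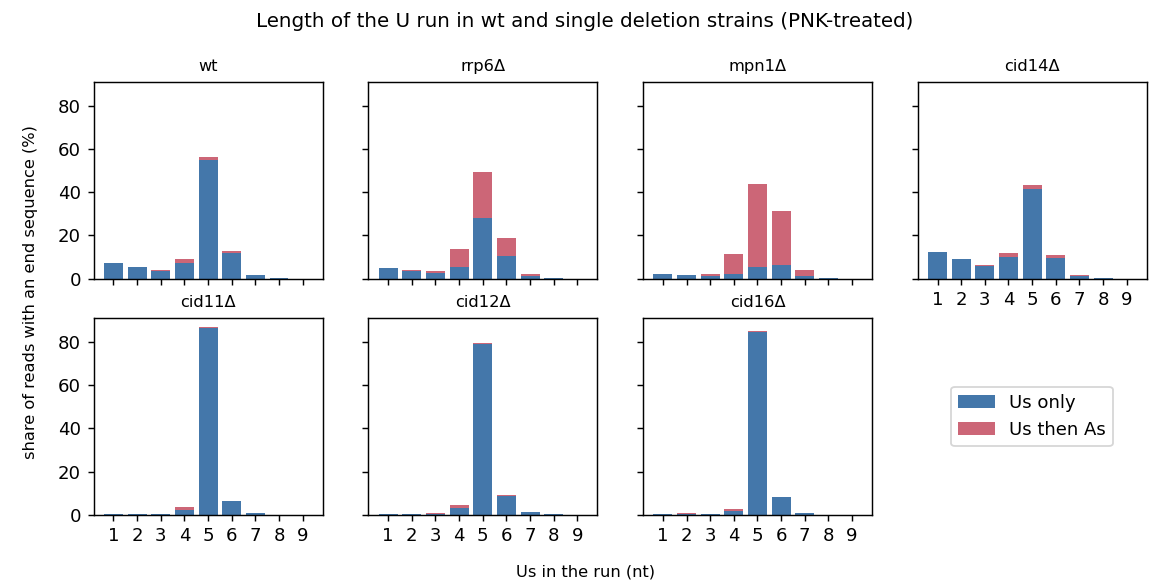
Share of reads with an end sequence (vertical axis, %) by the number of Us in the run (horizontal axis, nt) in wt and the 6 single deletion strains, 1 PNK-treated library each, with reads that carry As after the Us stacked on those that do not. The 5-U length is the commonest in all 7 panels, and reads with As make up most of it in mpn1Δ alone.

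The deletion of mpn1 was present in 5 backgrounds, namely wt, rrp6Δ, cid14Δ and both tagged strains, which gives a spread for its effect. Adenylated ends of endogenous U6 were higher without mpn1 in 5 of 5 pairs, by 58.8 ± 13.5 percentage points (SD, n = 5 pairs), and the range was 36.7 in rrp6Δ to 71.9 in wt. In rrp6Δ the share with mpn1 was already 39.1%, so a rise of 71.9 points was not possible there. The mean difference over pairs was 58.5 ± 13.3 points for ends in A and -57.7 ± 13.2 points for ends in U. The mean U run was longer in 5 of 5 pairs, by 0.411 ± 0.209 nt. Reads with no base past the constant part were fewer in 5 of 5 pairs, with a mean difference of -1.91 ± 1.47 points. For each of the 5 outcomes the two-sided exact sign-flip test gave p = 0.0625 (adjusted 0.0625), which is the smallest that 5 pairs allow, so this test could not pass 0.05. The mean differences with each distinct end of at least 2 reads counted once were 0.406 points for adenylated ends (exact sign-flip p = 0.375), 3.11 points for ends in A, -2.40 points for ends in U and 0.159 nt for the mean U run.

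**Figure D3:**
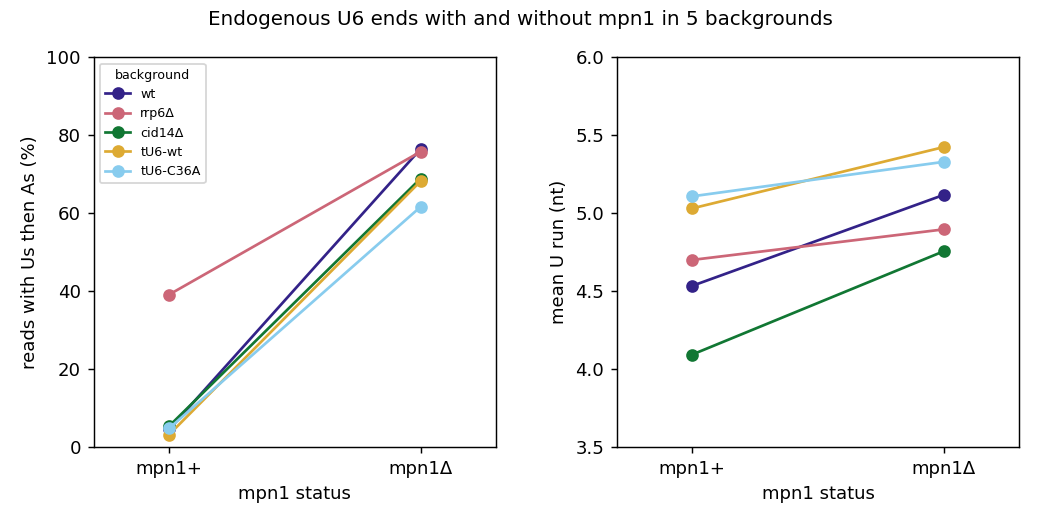
Adenylated share of endogenous U6 reads (left, %) and mean U run over reads with and without As (right, nt, the axis does not start at 0) for 5 backgrounds with mpn1 and without it. Each point is 1 library and each line joins the libraries of 1 background. All 5 lines rise in both panels.

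Over all PNK-treated libraries, the 5 mpn1-deleted strains had 70.2 ± 6.11% adenylated ends (SD, n = 5) and the 8 mpn1-positive strains 8.08 ± 12.6% (SD, n = 8). The highest mpn1-positive value, 39.1% in rrp6Δ, lay below the lowest mpn1-deleted value, 61.6%. The two-sided exact permutation test gave p = 0.000777 (Benjamini-Hochberg adjusted over 5 outcomes 0.00130), the smallest that 1287 regroupings allow. Ends in A and ends in U gave the same p. The mean U run, 5.10 ± 0.282 nt against 4.82 ± 0.355 nt, did not pass (exact permutation p = 0.156, adjusted 0.195), nor did reads with no base past the constant part (exact permutation p = 0.520, adjusted 0.520). These p-values measure the spread between strains that also differ in other genes. Within the 6 untagged libraries of 1 set the difference in adenylated share was 57.4 points (exact permutation p = 0.1, the smallest that 3 against 3 allow), and within the tagged strains it was 60.9 points (exact permutation p = 0.333, the smallest that 2 against 2 allow). With each distinct end of at least 2 reads counted once, the difference over all 13 libraries was 1.03 points and the call was lost (exact permutation p = 0.251). That setting gives every end the same weight, so it describes the variety of ends and cannot decide whether shares of reads differ.

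The double deletions show how rrp6 and cid14 acted on ends in cells without mpn1. Deleting rrp6 raised adenylated ends by 34.6 points in cells with mpn1, and in mpn1Δ the share was 75.8% with the second deletion and 76.5% without it, a difference under the limit. The difference between the effects was -35.3 points (counting interval -35.4 to -35.1). A rise of 34.6 points from 76.5% would exceed the whole, so the scale of shares itself sets part of this difference. In mpn1Δrrp6Δ the end with 6 Us and 1 A held 14.7% against 23.1% in mpn1Δ, and that with 5 Us and 1 A held 39.4% against 35.1%. Deleting cid14 moved the adenylated share by 0.834 points with mpn1 and by -7.57 points without it, neither past the limit, and the difference between these effects was -8.41 points (-8.58 to -8.23). Ends with 1 to 3 Us rose with the loss of cid14 in both settings, from 4.88% in mpn1Δ to 9.97% in cid14Δmpn1Δ. As a share of adenylated reads, tails of 3 or more As were rarest in the cid14 deletions among the 11 untagged libraries. They held 0.339% in cid14Δ and 0.172% in cid14Δmpn1Δ, against 2.80% in wt and 0.747% in mpn1Δ. Of all reads they held 0.0183% in cid14Δ and 0.119% in cid14Δmpn1Δ, against 0.127% in wt and 0.571% in mpn1Δ. By that measure cid11Δ, at 0.0648%, and cid16Δ, at 0.0911%, lay below cid14Δmpn1Δ. With 1 library in each cell of these designs no test was possible, and both differences between effects in adenylated share changed sign, to 0.383 and 0.757 points, when each distinct end of at least 2 reads was counted once.

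PNK was left out of 1 library each of wt and rrp6Δ, which shows the ends that could be ligated without it. Without PNK, adenylated ends held 14.6% of reads in wt (14.6 to 14.7) against 4.55% with it, past the limit, and 55.3% in rrp6Δ (55.2 to 55.5) against 39.1%, a difference of 16.2 points that stayed under the limit of 1.5 times. The 5-U end was lower in both strains, at 34.2% against 55.0% in wt and 8.31% against 28.1% in rrp6Δ. The 6-U end went opposite ways, with 20.8% against 11.9% in wt and 5.10% against 10.5% in rrp6Δ. In rrp6Δ the 13 A-tailed ends with at least 100 reads in both libraries held 1.26 to 1.99 times their share with PNK. The wt libraries came from sets that differ in reads holding an N (0.0244% without PNK, 0 with it), and the rrp6Δ libraries had at most 0.000142%. With each distinct end of at least 2 reads counted once, the differences in adenylated share were 0.584 points in wt, under the limit, and 1.03 points in rrp6Δ.

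**Figure D4:**
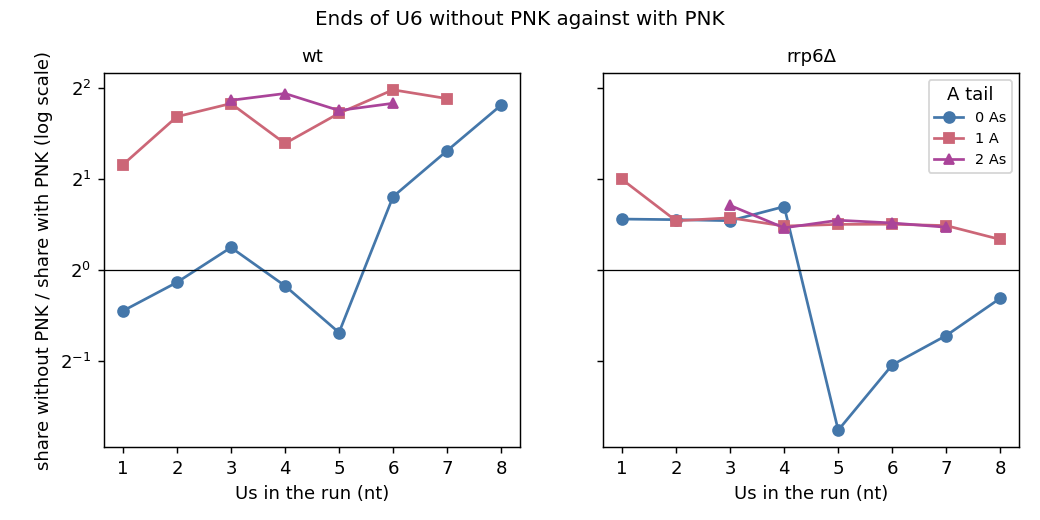
Share of an end without PNK divided by its share with PNK (vertical axis, log scale) against the number of Us in the run (horizontal axis, nt) for wt (left) and rrp6Δ (right), with 1 library per strain and treatment. Ends with 0, 1 or 2 As are drawn separately. In rrp6Δ the 5-U end lies at 0.296 and the end with 5 Us and 1 A at 1.41.

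In the 4 tagged strains, tagged and endogenous U6 came from the same RNA. Their mean U runs were 5.19 nt for tagged and 5.22 nt for endogenous U6, a difference of -0.0292 ± 0.126 nt (SD, n = 4 strains; two-sided exact sign-flip p = 0.75, adjusted 0.875). Adenylated ends differed by -1.39 ± 4.72 points (exact sign-flip p = 0.625, adjusted 0.875), with tagged U6 higher in the 2 strains with mpn1 and lower in the 2 without it. With 4 strains the smallest possible p is 2 of 16 sign patterns, so this test could not pass 0.05. Without mpn1Δ tU6wt the adenylated difference was 0.171 points, and without tU6-C36A the difference in mean U run was 0.0247 nt, so both directions rest on 1 strain. They also turned with the processing: the adenylated difference was 0.248 points with each distinct end of at least 2 reads counted once, and that in mean U run 0.0428 nt with ends of 4 and 19 nt left out, an alternative chosen after seeing the data. Loss of mpn1 raised adenylated ends of tagged U6 as well, from 4.11% to 62.1% in the strain with wild-type tagged U6 and from 8.92% to 57.1% in the strain with C36A. The endogenous files of these strains listed few ends of 4 nt: the 4-U end held 0.00905% to 0.0385% there and 2.58% to 5.03% in tagged U6. The end with 4 Us and a C held 0.627% to 3.18% of endogenous U6, where it was the third commonest end of tU6-wt, and 0.00514% to 0.0116% of tagged U6. By the labels the ligated adapter starts with a C, so whether this C belongs to U6 is not known.

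C36A is a change in the tagged U6, counted from 1 at the first annotated base; it lies in exon 1, in the ACAGAGA sequence that pairs with the 5′ splice site. With mpn1 present, adenylated ends held 8.92% (8.85 to 8.99) of tagged U6 with C36A and 4.11% (4.08 to 4.15) of tagged wild-type U6, a difference of 4.80 points that stayed under the limit, and that passed it at 5.12 points when ends of 4 and 19 nt were left out and at 6.87 points when each distinct end of at least 2 reads was counted once. Of adenylated reads, 26.4% carried 3 or more As with C36A and 1.57% with the wild-type sequence, or 2.35% and 0.0644% of all reads. Tails of 2 As went the other way, at 1.34% and 20.6% of adenylated reads. The end with 5 Us and 2 As alone held 10010 of the 10291 reads with 2 As in tagged wild-type U6, and 39 of 710 with C36A. These files held 1816 (wild-type) and 1054 (C36A) distinct ends, against 3324 in untagged wt. Without molecular identifiers, many copies of few molecules cannot be told apart from many molecules here. Tails of 1 A held 6.44% and 3.20% of all reads. The 5-U end held 35.4% against 61.4%, the 6-U end 25.1% against 17.9%, and ends with 1 to 3 Us 12.7% against 3.81%. Endogenous U6 of the same libraries had 1.41% and 4.20% of ends with 1 to 3 Us, so the difference there, under the limit, had the other sign, and the difference between the effects in the 2 forms was 11.7 points. Without mpn1 the adenylated share of tagged U6 was 57.1% with C36A and 62.1% with the wild-type sequence, a difference of -5.00 points under the limit, which was -3.14 and -0.135 points under the same 2 alternatives. The end with 6 Us and 1 A held 27.9% against 22.8%, and that with 5 Us and 1 A 20.4% against 27.5%.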

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

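All tests of explanations below were chosen after the result was seen.

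Among the 8 mpn1-positive PNK-treated libraries, rrp6Δ stood far from the others, with 39.1% adenylated ends, 40.9% ends in A and 57.8% ends in U. The library of cid14Δ stood apart in reads with no base past the constant part, at 6.78%. These were 4 values over 10 sets of libraries examined, where chance marks about 1 set in 20, and the 3 values of rrp6Δ measure nearly the same reads.

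Several effects had opposite signs in different settings, each from single libraries, and none of these differences was tested. Effects under 1 percentage point or 0.1 nt were not considered, a limit set after the data were seen. Deleting rrp6 moved the mean U run by 0.166 nt with mpn1 and -0.221 nt without it, and by -0.349 nt in RNA not treated with PNK. Leaving out PNK moved it by 0.227 nt in wt and -0.289 nt in rrp6Δ. The values of -0.349 and 0.227 nt both involve wt without PNK, whose library set differed from that of the library it was compared with. Set cannot be told apart from deletion or treatment there. The C36A strains differed from the wild-type tagged strains in adenylated share by 4.80 points with mpn1 and -5.00 points without it in tagged U6. In their endogenous U6, which lacks the mutation, the differences were 1.59 and -6.57 points. Tagged minus endogenous adenylated share was 4.10 points in tU6-C36A and -4.48 points in mpn1Δ tU6-C36A. With each distinct end of at least 2 reads counted once, 4 of these 6 contrasts no longer had opposite signs. Deleting rrp6 then moved the mean U run by -0.241 nt with mpn1, -0.153 nt without it and -0.525 nt in RNA not treated with PNK, and leaving out PNK moved it by 0.315 nt in wt and 0.0306 nt in rrp6Δ. The C36A strains then differed by 0.931 and 0.352 points in endogenous U6.

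In rrp6Δ, the 5-U to 7-U ends held smaller shares without PNK and A-tailed ends larger ones. Recovery by product length as the whole cause is argued against, because the ratios of ends with 4, 5 and 6 Us and 1 A were 4.72, 2.91 and 2.33 times those of the equally long ends of Us alone. Blocked 3′ ends on the 5-U to 7-U ends, and a change in the RNA between preparations, stay open. The A-tailed ends moved by nearly 1 factor (SD of their log2 ratios 0.157) and the 1-U to 4-U ends by a like factor of 1.45 to 1.62, but shares sum to 100%, so any fall of the 5-U to 7-U ends gives this. A difference between library sets cannot be told apart either, since both libraries were put in 1 set by the share of reads holding an N (0.000142 percentage points apart) and the labels give no batch. In wt the 5-U end fell to 0.622 times its share with PNK, while the 6-U and 7-U ends rose to 1.75 and 2.47 times. The wt libraries came from different sets, so these values cannot decide between the explanations.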

How the results depend on the processing

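The mean differences between mpn1-deleted and mpn1-positive libraries, over pairs and over all PNK-treated libraries, kept their direction under all alternatives run. The U run of reads of Us alone was not among them, and it went both ways over the pairs. The differences over 5 pairs ranged from 55.5 to 64.3 points (adenylated), 55.1 to 63.9 (ends in A), -62.9 to -54.1 (ends in U), 0.348 to 0.465 nt (mean U run) and -2.35 to -1.35 points (reads with no base past the constant part) with 1 pair left out. Over libraries, with 1 left out, they ranged from 60.5 to 66.5, 60.6 to 66.6, -66.5 to -60.7, 0.181 to 0.372 nt and -1.24 to -0.151, and no call changed. Tagged minus endogenous U6 ranged from -3.22 to 0.171 points and from -0.0706 to 0.0247 nt with 1 strain left out, so its sign was lost without mpn1Δ tU6wt (adenylated) and without tU6-C36A (mean U run). The reads with no base were not recomputed under filters that do not touch them.

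Values of single libraries that left their counting interval follow, as differences from wt for rrp6Δ, mpn1Δ, cid14Δ, cid11Δ, cid12Δ and cid16Δ in that order, where 6 are given. With ends of at least 10 reads, adenylated differences were 35.0 for rrp6Δ, 72.5 for mpn1Δ and 10.2 for wt without PNK. With ends that reach the U run they were 34.8, 72.0 and 10.2, and 16.4 for rrp6Δ without PNK. None of these 20 single-library differences crossed the size limit under either choice.

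Counting each distinct end of at least 2 reads once removed the weight of the common ends. It describes the variety of ends, so it cannot decide whether shares of reads differ. Adenylated differences were -0.137, -0.463, -0.405, -0.406, -1.99 and -0.732 points, and those of the mean U run -0.241, 0.0928, 0.456, -0.135, 0.341 and -0.677 nt. Leaving out PNK gave 0.584 points and 0.315 nt in wt, and 1.03 points and 0.0306 nt in rrp6Δ. The differences between effects with and without mpn1 were 0.383 points and 0.0876 nt for rrp6 and 0.757 points and 0.322 nt for cid14. C36A gave 6.87 points and -0.323 nt with mpn1, and -0.135 points and 0.312 nt without it. Over the 13 libraries, mpn1 status lost its calls, at 2.84 points (ends in A), -0.980 (ends in U) and 1.03 (adenylated), and tagged minus endogenous was 0.248 points. Files with more adenylated than oligo-U ends went from 8 to 19, those with A as the commonest last base from 8 to 13, and those with a mean U run of at least 5 nt from 11 to 4. In all, 7 of 20 single-library differences crossed the size limit.

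The median U run reached 5 nt in 19 files, and with A tails of at least 2 As 0 files had more adenylated than oligo-U ends.

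The following alternatives were chosen after seeing the data. With the line without a sequence counted as 0 Us, adenylated differences were 33.9, 71.3, 0.615, -2.07, -1.29 and -2.34 points and mean U run differences 0.209, 0.680, -0.581, 0.629, 0.646 and 0.638 nt. Leaving out PNK gave 9.88 points and 0.254 nt in wt, and 15.3 points and -0.329 nt in rrp6Δ. The differences between effects were -34.5 points and -0.427 nt for rrp6 and -9.24 points and 0.141 nt for cid14. C36A gave 4.68 points and -0.178 nt with mpn1, and -4.55 points and 0.104 nt without it. With ends of 4 and 19 nt left out, adenylated differences were 36.4, 73.3, 1.11, -2.41, -1.63 and -2.69 points and mean U run differences 0.174, 0.578, -0.475, 0.462, 0.492 and 0.468 nt. Leaving out PNK then gave 10.3 points and 0.251 nt in wt and 19.5 points in rrp6Δ. The differences between effects were -36.5 points for rrp6 and -7.76 points and 0.119 nt for cid14. C36A gave 5.12 points and -0.149 nt with mpn1, and -3.14 points and 0.0678 nt without it, and tagged minus endogenous was 0.0428 nt. Without the endogenous files of tagged strains, 7 of 15 files had a mean U run of at least 5 nt, and without the libraries with most reads holding an N, 8 of 15 did. Reading ends of 5 nt in C without the C changed no direction or call among 37 results, and tagged minus endogenous was then -0.00784 nt. Apart from the weighting, which gives all ends of at least 2 reads the same say, the cause was not tested. At these depths counting error is small beside the differences between settings. Without replicates the spread between libraries of the same strain was not measured.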

Other observations

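The tests of explanations in this part were chosen after the results were seen.

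Adenylation varied with the length of the U run. In mpn1Δ, 87.4% of reads with 5 Us carried As, against 81.5% with 4 Us, 79.5% with 6 Us and 2.83% with 1 U. In wt the highest share was at 4 Us, with 18.7%, against 2.48% at 5 Us. Among reads of cid11Δ, cid12Δ and cid16Δ the 4-U run carried As in 41.4%, 37.0% and 44.1% of cases and the 5-U run in 0.515%, 0.80% and 0.436%. In cid12Δ, 11.1% of adenylated reads had 3 or more As, against 2.80% in wt. That share was higher still in tagged U6 of tU6-C36A, at 26.4%.

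Ends with 1 to 3 Us were few in cid11Δ, cid12Δ and cid16Δ compared with wt. A loss of shorter products as the whole cause is argued against, because the 6-U end was lower as well (median 0.683 times wt over the 3 strains). A cause shared by their library set could not be excluded: wt without PNK, the only other library of the set, had 14.5% of such ends, but it is 1 library prepared differently. A role of the deleted genes, the biological explanation, cannot be told apart from the set either. Endogenous U6 of the tagged strains with mpn1, where these genes were not deleted, had at most 4.20% of such ends, so low values may also arise without the deletions.

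Ends of 4 nt were nearly missing from the endogenous files of the tagged strains. The absence of U6 with 4 Us from these cells, a biological explanation, is argued against, because the end with 4 Us and 1 A held at least 1.46 times its tagged share in 3 of the 4 strains and 1.02 times in the other. A loss of ends by length as the whole cause is argued against too, because it would not raise the 5-nt end of 4 Us and a C, whose lowest share in these 4 files was 5.0 times the highest in the other 15. An added C, in the cells or when the files were made, stays open as a candidate explanation: the end of 3 Us, 1 A and a C was also commonest in these 4 files, but by only 1.46 times in tU6-C36A, with 62 reads. The ligated adapter starts with a C by the labels, so an adapter base left on the read would give the same ends. A loss beside an added C cannot be told apart from an added C alone, since the end of 3 Us and 1 A without a C, at most 0.00754 times its tagged share, would be low under both.

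Distinct ends of 19 nt were few in all 19 files, at 0.0495 to 0.346 times the mean number of those of 18 and 20 nt. Tails of at least 15 nt after the U run held 1.21% to 4.01% of reads in the files of tagged strains, 1.32% in cid12Δ and 0.316% to 0.682% in the other 10 files. Of these long-tailed reads, 0.415% to 32.7% held a stretch like the start of the adapter, with up to 4 mismatches, and wt without PNK had the most. The other tails were placed by their first 15 nt. Of the long-tailed reads, 6.10% to 61.2% matched annotated rRNA in that way and 4.93% to 35.0% a tRNA. A further 15.4% to 64.8% had no exact match.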
